A study of Homo sapiens with 4 samples.

How the data were processed

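Ribosome profiling was used on HEK 293 cells, an established human embryonic kidney line. Ribosome profiling sequences the short mRNA fragments (footprints) that ribosomes protect from RNase, so a read reports where a ribosome stood. Per the labels' protocols, cells in 10 cm dishes received 10 ug of a plasmid that expresses a suppressor tRNA (sup-tRNA) or of the empty vector, with Fugene6, and were lysed 48 h later in buffer with cycloheximide. Each group had 2 libraries, which the labels call biological replicates. No matched RNA-seq was analysed here, so footprint changes were not divided by mRNA levels.

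The data were 1 table with 8113 Ensembl transcripts, 1 row each. Reads were aligned with STAR 2.7.1a against GRCh38, per the submitters' processing notes. The annotation release, read-length limits, treatment of reads that map to several places, and the rule that chose the transcripts are not given in the sources used here. The deposited counts are whole numbers of footprint reads per library in the coding sequence and in the readthrough region. Per the file headers the readthrough region lies in the 3' UTR, and a further column gives the length to a termination codon there. In the first row the region was 6 nt shorter than that length, and the difference in the other rows is not given here. The deposited signal columns hold the density of reads per nt in each region, not scaled to library depth. The deposited ratio, named RRTS in the file headers, equalled the readthrough density divided by the coding density of the same library, with 0 transcripts deviating by more than 1e-09. The authors' average RRTS per group equalled the mean of the 2 replicates and was not used further. Because RRTS is a ratio within a library, it carries no correction for a difference between libraries in background reads after the stop codon.

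Readthrough regions were 9 to 942 nt long, with a median of 60.0 nt, against a median coding sequence of 1413 nt. In 254 transcripts the region length was not divisible by 3. Counts in all columns were identical to those of another row for 6 transcripts, and 39 transcripts with over 20 readthrough reads shared their readthrough counts and region length with another row; such rows share reads and are not independent. Coding-sequence totals ran from 20572548 to 24521550 reads per library. Depth was far lower after the stop codon: the median transcript had 5, 5, 5 and 4 readthrough reads in sup-tRNA replicates 1 and 2 and control replicates 1 and 2. Intervals for shares of reads are 95% Wilson intervals and cover counting error only, as does the floor of 3 counts used where a group had 0 reads. Coding-sequence counts of all 6 pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 8.48 to 28.4), so no library was a repeat of another.

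Tests were fixed before the data were examined. Transcripts entered the readthrough tests with RRTS above 0 in at least 2 of the 4 libraries and at least 50 coding-sequence reads in each, which left 7226. Library medians of RRTS were compared with an exact two-sided permutation test, whose smallest possible p with 2 against 2 libraries is 0.333. Per transcript, the planned test was limma 3.58.1 with a mean-variance trend on log2(RRTS + 0.001). Because the table also held counts for both regions, the region-by-group interaction of edgeR 4.0.16 is given beside it and called the count model. This interaction was fixed at the same time, but only as an alternative to limma. Its settings (quasi-likelihood, with coding-sequence totals as library sizes for both regions) and its place ahead of limma in the results were not part of that plan. Coding-sequence counts were tested with edgeR's quasi-likelihood test after TMM normalization and filterByExpr, and levels are given as CPM (reads scaled to the normalized library size). All p-values per transcript were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. DESeq2 1.42.0 was run as an alternative. Values were not centred between libraries, since a shift of all transcripts was part of the question.

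Other choices were made after the data had been seen. A set of 2764 well-covered transcripts was defined by a coding-sequence density that would give at least 100 reads in the readthrough region at equal density, with at least 50 coding-sequence reads in each library. This definition uses no readthrough reads. Shares of transcripts with more than 2-fold change in this set, comparisons of pairs of libraries, and the classes by control RRTS were also chosen then. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.

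The tests were tried on simulated counts for the real transcripts with 200 of them changed. Among 7030 simulated transcripts that passed the readthrough filter, limma called 0 of the 50 transcripts raised 4-fold, and the count model called 26 of 50, with 1 false call among 6837 unchanged ones. For 2-fold rises the count model called 3 of 50, and for 4-fold falls 9 of 46. In the 2700 simulated well-covered transcripts the count model called 14 of 16 raised 4-fold and limma 6 of 16. The coding-sequence test called all 50 transcripts at each fold size, with 6 false calls among 7026 unchanged ones. The simulation gave all transcripts the same spread between libraries and changed only 200, which makes an adjusted threshold harder to pass. Its rates of true and false calls therefore need not hold for the real data.

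Transcripts to be named were to be the 12 with the highest and the 12 with the lowest log2 change past the threshold, with groups that do not overlap, and the 5 with the highest control RRTS. None of the 8113 transcript IDs (0 matched) was paired with a gene name by the gene table used here (assembly GRCh38.p14), and no genome sequence was used here. At most 2 identifiers that rose and 2 that fell are therefore printed, 1 in each direction for readthrough and for coding sequences, and the others are described by their values. For risen readthrough the identifier printed is the highest-ranked one that the count model also called, a choice made after its values were seen. For the same reason the planned comparisons by stop codon, by next base and by gene list, and the use of 1 transcript per gene, were not run.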

Results

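Ribosome footprints were counted in HEK 293 cells 48 h after transfection with a sup-tRNA plasmid (2 libraries) or with the empty vector (2 libraries). A suppressor tRNA pairs with a stop codon and inserts an amino acid, so that the ribosome goes on into the 3' UTR until it meets another stop codon. The series concerns chimeric pyrrolysine tRNAs that place alanine at premature stop codons; the stop codon read by the plasmid's tRNA is not given in the labels. The stated question was how this tRNA affects readthrough at the cells' own stop codons. Readthrough was measured as RRTS, the footprint density between the annotated stop codon and the next termination codon divided by the density in the coding sequence. An RRTS of 0.1 means that the region after the stop held 10% of the coding density. The ratio counts all footprints in that region, whatever their source. The labels call the libraries biological replicates and say nothing further of their origin, so p-values measure the spread between these samples.

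Coding-sequence reads numbered 20572548 and 23827768 in the sup-tRNA libraries and 24521550 and 22189600 in the control libraries. Readthrough regions held 178181 and 181590 reads with the sup-tRNA, against 152341 and 106371 with the empty vector. As a share of all reads in the table this was 0.859% (95% Wilson interval 0.855 to 0.863) and 0.756% (0.753 to 0.760) with the sup-tRNA. In control cells it was 0.617% (0.614 to 0.621) and 0.477% (0.474 to 0.480). The group means were 0.808% ± 0.072 and 0.547% ± 0.099 (SD, n = 2), a ratio of 1.48, and the lower sup-tRNA library exceeded the higher control library 1.22-fold. The exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow. These counting intervals are far narrower than the differences between replicates.

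The first comparison asked whether readthrough of all transcripts shifted. Over the 7226 tested transcripts the median RRTS was 0.114 and 0.101 in the sup-tRNA libraries and 0.0938 and 0.0736 in the control libraries. The group means of these medians were 0.108 ± 0.0090 and 0.0837 ± 0.0143 (SD, n = 2), a ratio of 1.28. The ratio between single libraries of the 2 groups ran from 1.08 to 1.55. The 2 control libraries differed from each other by a ratio of 1.27, so the shift of the median was about as large as the spread between control replicates (exact permutation p = 0.333). The upper part of the distribution differed more than the lower part, though only slightly over all tested transcripts. Over the 7226 the ratio of group means was 1.22 at the 25th percentile and 1.36 at the 90th. Between single libraries it ran from 1.02 to 1.49 and from 1.14 to 1.64, so these ranges overlapped. Among the 2764 well-covered transcripts the 25th percentile of RRTS was 1.19 times as high with the sup-tRNA, the median 1.29 times, and the 90th percentile 1.51 times (0.307 ± 0.029 against 0.204 ± 0.033, SD, n = 2). At the 90th percentile the control libraries differed from each other 1.26-fold, and the closest pair of a sup-tRNA and a control library also differed 1.26-fold. RRTS was above 0.5 for 4.45% and 3.58% of well-covered transcripts with the sup-tRNA and for 1.48% and 0.977% in control cells.

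**Figure D1:**
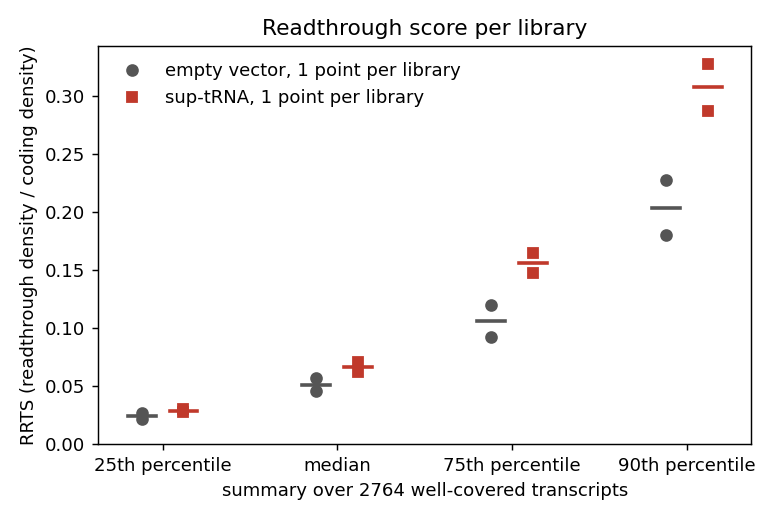
RRTS (readthrough density over coding density, no unit) at 4 percentiles of the 2764 well-covered transcripts. Each point is 1 library and each bar a group mean of 2; at the 90th percentile the sup-tRNA libraries stood at 0.328 and 0.287 and the control libraries at 0.227 and 0.180.

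The second comparison asked which transcripts changed. Readthrough rose on a subset of transcripts, while most passed no threshold. In the count model 601 of the 7226 transcripts (8.32%) rose and 5 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test; 1006 higher and 101 lower at an unadjusted p under 0.05). For the 601, the median RRTS was 0.375 and 0.324 in the sup-tRNA libraries and 0.0598 and 0.0491 in the control libraries, and in all 601 both sup-tRNA values lay above both control values. Among all tested transcripts this order held for 28.1% and the opposite order for 13.8%, where chance gives 16.7% each. The threshold itself favours transcripts with this order, so its presence in all 601 is no separate support. The median fold of the 601, from reads summed over each group, was 5.41 with an interquartile range of 3.53 to 9.10. More than 4-fold higher were 404 of them, more than 8-fold 186 and more than 16-fold 54. These folds set the 21 transcripts without a control read at a floor of 3 counts for the group. The 601 were picked on the same reads by a test that finds large rises more readily, so their folds can overstate the rise. In 184 of the 601, mean RRTS with the sup-tRNA passed 0.5. The transcripts not called in either direction had median RRTS values of 0.101 and 0.0893 with the sup-tRNA and 0.0988 and 0.0768 in control cells. Their count-model log2 change had an interquartile range of -0.38 to 0.55, on a median of 23 readthrough reads over the 4 libraries. With so few reads a missing call does not show a lack of change, so 601 counts detected rises only.

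The 5 transcripts that fell in the count model had median RRTS values of 0.00814 and 0.0316 with the sup-tRNA and 0.172 and 0.207 in control cells, on a median of 18 reads. In 1 of the 5 the coding-sequence count, the denominator, also rose 2.77-fold, mainly in sup-tRNA replicate 1. Where readthrough columns were scaled on their own totals, which removes the 1.48-fold difference in the share of readthrough reads whichever transcripts carry it, the count model gave 448 higher and 255 lower transcripts instead of 601 and 5. The number of lower calls therefore depended on the scaling. With DESeq2 on the same counts 322 rose, all of them among the 601 (322 shared), and 0 fell.

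**Figure D2:**
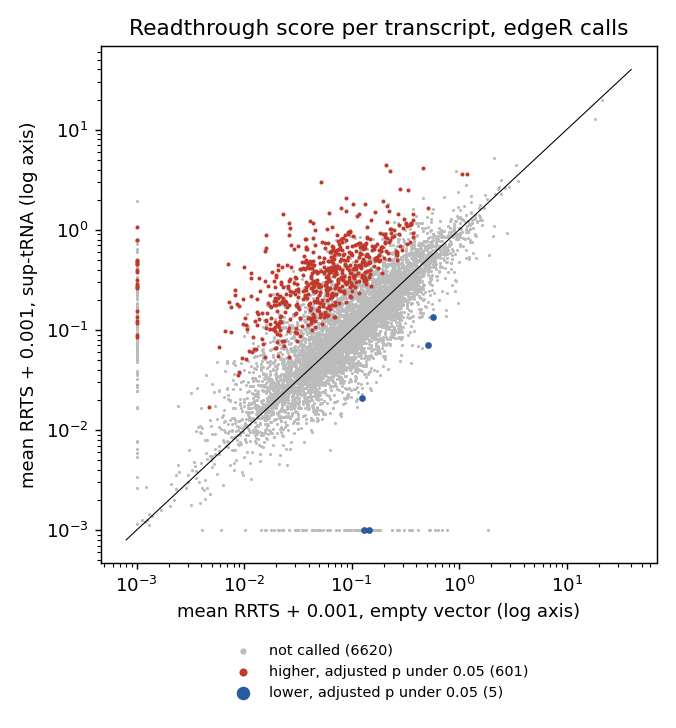
Mean RRTS + 0.001 of each tested transcript in control cells (horizontal, log axis) and with the sup-tRNA (vertical, log axis); the line marks equal values. The 601 transcripts that rose in the count model lie above the line, the 5 that fell lie below it, and points at the left and lower edges have 0 reads in a whole group.

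The planned test of the ratio itself, limma on log2(RRTS + 0.001), gave 183 higher and 48 lower transcripts out of 7226 (890 higher and 176 lower at an unadjusted p under 0.05). Of the 183, 121 also rose in the count model, and 2 of the 48 also fell there. Limma called 0 higher and 0 lower with a pseudocount of 0.0001 (886 and 186 at an unadjusted p under 0.05), with centring on the median (745 and 443) and with quantile normalization (721 and 483). Many of these calls rested on few reads: 81 of the 183 had 0 control reads, and 47 of the 48 had 0 sup-tRNA reads, with a median of 3 reads over the 4 libraries. With the 81 at the floor of 3 counts, the median fold of the 183 was 6.35. When any 1 of the 4 libraries was left out, which leaves 1 residual degree of freedom, limma called 0 in both directions at an adjusted p under 0.05, and 507 to 1296 higher and 143 to 370 lower at an unadjusted p under 0.05. Among all 7030 simulated transcripts this test called 0 of 50 raised 4-fold, against 6 of 16 in the simulated well-covered set. Few transcripts were changed in the simulation, which makes the adjusted threshold harder to pass, so these counts do not measure the test's power in the real data. The count model without 1 library called 429 to 654 transcripts higher.

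All 12 transcripts with the highest log2 change past the limma threshold had 0 control reads, and all 12 with the lowest had 0 sup-tRNA reads. Of the former 5 also rose in the count model, and of the latter 0 fell there. ENST00000296215, with a readthrough region of 15 nt, had 9 and 7 readthrough reads with the sup-tRNA and 0 in both control libraries. Its RRTS with the sup-tRNA was 1.08 ± 0.29 (SD, n = 2), at least 4.74-fold higher than the control floor of 3 counts over the group (limma adjusted p = 0.0457, edgeR adjusted p = 0.00931). With 1.28 and 0.870 in the 2 libraries, footprints after the stop were about as dense as in the coding sequence. A value this high over 15 nt is not by itself a measure of readthrough. The transcript ranked above ENST00000296215 had 5 reads with the sup-tRNA and 0 in control cells, at least 1.73-fold above the floor (limma adjusted p = 0.0457, edgeR adjusted p = 0.178). ENST00000234142 headed the list in the other direction with 0 sup-tRNA reads and 1 and 2 control reads, too few for a fold (limma adjusted p = 0.0457, edgeR adjusted p = 0.415). For both printed transcripts the limma adjusted p became 0.0544 with a pseudocount of 0.0001, 0.0550 with centring and 0.0603 with quantile normalization. Over all alternatives run, the adjusted p ranged from 0.00931 to 0.194 for ENST00000296215 and from 0.0145 to 0.812 for ENST00000234142.

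The size of the change was described in the 2764 well-covered transcripts, where few reads matter less. RRTS more than doubled in 532 of them (19.2%), rose more than 4-fold in 274 (9.91%) and more than 8-fold in 110 (3.98%), while it more than halved in 102 (3.69%). It stayed within 1.5-fold in 64.0%, and the median log2 change was 0.11. In 100 simulations without an effect, 4.20% of these transcripts more than doubled and 4.45% more than halved on average. The simulations gave all transcripts the same spread between libraries. The share that more than halved was no larger than in these simulations. They held no shift of all transcripts, and an upward shift by itself lowers this share, so real falls are not excluded. For each of the 4 pairs of a sup-tRNA and a control library, between 18.0% and 26.8% more than doubled and between 9.30% and 13.1% rose more than 4-fold. In the same pairs between 4.52% and 9.88% more than halved, and the median log2 change ran from -0.05 to 0.37. The highest share halved and the lowest median both came from sup-tRNA replicate 2 against control replicate 1. Between the 2 sup-tRNA libraries 7.74% differed more than 2-fold in the direction of replicate 1, and between the 2 control libraries 13.1% did; in the opposite direction 4.63% and 4.20% did. Beyond 4-fold these within-group shares were 1.95% and 3.08%. Rises of more than 4-fold were more frequent in each of the 4 pairs across groups than in either pair within a group.

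**Figure D3:**
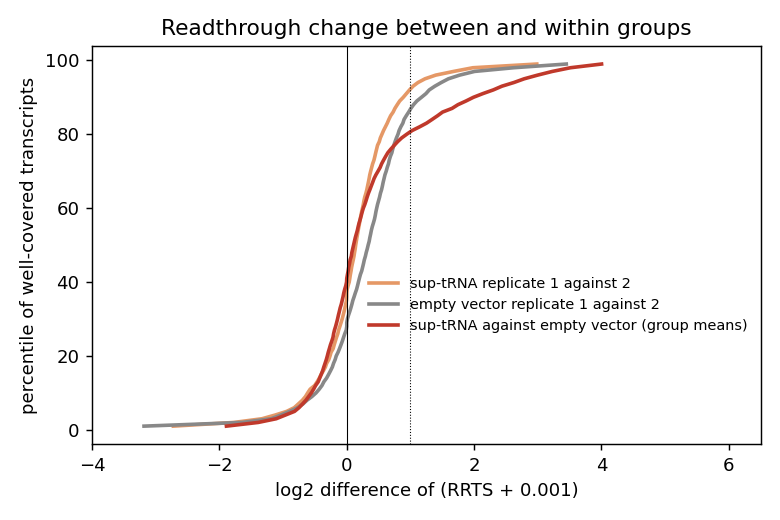
Cumulative distribution of the log2 difference of RRTS + 0.001 over the 2764 well-covered transcripts (horizontal axis in log2 units, vertical axis the percentile from 1 to 99; the dotted line marks a doubling). The curve between the group means runs with the within-group curves in its lower part and reaches a log2 difference of 1.99 at the 90th percentile, against 0.89 between the sup-tRNA libraries and 1.17 between the control libraries.

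The same transcripts rose in separate pairs of libraries. Of the 550 well-covered transcripts that more than doubled between sup-tRNA replicate 1 and control replicate 1, 412 (74.9%) also more than doubled between the replicate 2 libraries, against 22.9% of all well-covered transcripts and 9.94% of those that had not doubled in the first pair. Transcripts with over 8-fold rises had median RRTS values of 0.0312 and 0.0196 in control cells and 0.336 and 0.296 with the sup-tRNA. For rises of 4- to 8-fold the medians were 0.0440 and 0.0354 in control cells and 0.242 and 0.205 with the sup-tRNA. The 2130 transcripts within 2-fold had 0.0652 and 0.0512 in control cells and 0.0626 and 0.0548 with the sup-tRNA. These size classes were set on the same RRTS values of all 4 libraries. Their medians therefore describe the classes and are no separate support for the rises.

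Transcripts with a high control RRTS doubled less often, an order that held for folds and not for absolute gains. With classes set on control replicate 1 and changes measured against control replicate 2, 26.1% of 1419 transcripts with an RRTS of 0.02 to 0.1 more than doubled, against 11.4% of 351 at or above 0.2 (Fisher's exact test over transcripts, odds ratio 2.75, p = 8.69e-10). With the control libraries exchanged the shares were 20.4% of 1485 and 2.78% of 216 (Fisher's exact test, odds ratio 8.97, p = 5.47e-13). The 90th percentile of the gain in RRTS was 0.167 in the low class and 0.240 in the high class with classes on control replicate 1, and 0.162 and 0.168 with the libraries exchanged. At a control RRTS of 0.2 to 0.5, 22.3% gained and 0.645% lost more than 0.1 with classes on control replicate 1. With the libraries exchanged 18.5% gained and 18.0% lost as much, so gains there were matched by losses. Halving was also rarer at high control RRTS: 4.69% of transcripts at 0.02 to 0.05 and 0 of 310 at 0.2 to 0.5, with classes on control replicate 1. Transcripts are not independent replicates, so these p-values describe these libraries only. In the class of 0.2 to 0.5 alone, 12.3% of 310 and, with the libraries exchanged, 3.17% of 189 more than doubled. Mean control RRTS was above 1 in 91 tested transcripts, that is, the region after the stop was denser in footprints than the coding sequence. Readthrough of the stop codon alone would give no such excess at equal ribosome speed in both regions, so a high RRTS is not by itself a measure of readthrough. The 5 transcripts with the highest mean control RRTS had 21.4, 18.3, 3.57, 3.39 and 2.90, and 19.9, 12.8, 3.06, 4.44 and 2.65 with the sup-tRNA. None of these 5 passed the threshold in limma or the count model (lowest edgeR adjusted p = 0.476).

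The last comparison concerned ribosome footprints on coding sequences. Of 8109 transcripts tested, 208 rose and 152 fell (edgeR quasi-likelihood test, adjusted p under 0.05; 1727 at an unadjusted p under 0.05). Most changes were small: the median size of a called change was 0.36 on the log2 scale, 24 rose and 14 fell more than 1.5-fold, and 6 rose and 2 fell more than 2-fold. ENST00000216117 rose 11.98-fold, from 44.0 ± 3.7 to 526.5 ± 5.0 CPM (reads scaled to library size, SD, n = 2; edgeR adjusted p = 9.46e-10), while its readthrough passed no threshold (edgeR adjusted p = 0.609). ENST00000578186 fell 2.00-fold, from 1248 ± 108 to 623 ± 22 CPM (SD, n = 2; edgeR adjusted p = 1.49e-04). Another row carried nearly the same CPM as ENST00000578186 in all 4 libraries, so these 2 falls are 1 observation. The transcript with the second-highest rise, 2.77-fold, rested on sup-tRNA replicate 1, with 118 CPM there, 39.8 in sup-tRNA replicate 2 and 27.8 and 28.8 in the control libraries. Its readthrough was among the 5 falls of the count model (edgeR adjusted p = 0.0134), and a higher coding-sequence count lowers the ratio by itself. Without control replicate 1 the number of calls dropped to 88 higher and 68 lower.

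Coding-sequence falls and readthrough rises overlapped. Of 142 transcripts that fell in coding-sequence counts and were tested for both, 42 were among the 601 with risen readthrough, where independent lists would share 11.8 (Fisher's exact test over transcripts, odds ratio 4.90, p = 8.30e-14). Of 188 that rose in coding-sequence counts, 19 were among the 601, where independent lists would share 15.6 (Fisher's exact test, p = 0.349). Both tests use the same libraries and coding-sequence counts, so part of the overlap can come from chance values that they share. A real fall in coding-sequence counts also raises the readthrough ratio by itself, so independent lists are not a strict reference here. Over well-covered transcripts, coding-sequence CPM of those whose RRTS more than doubled changed by -0.055 (log2, SE 0.0090 over transcripts) relative to the other transcripts. For the same transcripts the difference was -0.016 between the 2 sup-tRNA libraries and 0.0014 between the 2 control libraries.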

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

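The count-model alternatives other than DESeq2, the offset model, the well-covered set and the shares of transcripts more than doubled were chosen after seeing the data. The planned comparisons by stop codon and gene list, and the use of 1 transcript per gene, were not run: no table used here pairs the identifiers with genes or sequences. The ratio of median RRTS kept its direction under every alternative run, from 1.15 without control replicate 2 to 1.46 without control replicate 1. Among the counts, ratios and shares followed, 47 alternatives stayed near the main value and 43 moved, where near means within 1.5 times for counts and within 1 SD for the ratio (0.245) and the share more than doubled (3.85 percentage points over 4 pairs of libraries). For transcripts followed singly, 44 alternatives kept direction and side of the threshold and 44 kept only the direction.

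The limma counts of 183 higher and 48 lower transcripts moved under most alternatives, and the cause was not tested. They became 0 and 0 with a pseudocount of 0.0001 (886 and 186 at an unadjusted limma p under 0.05), with centring on the median (745 and 443), with quantile normalization (721 and 483), and (range 0 to 0) without each of the 4 libraries (507 to 1296 and 143 to 370). They became 368 and 5 for transcripts above 0 in all 4 libraries, 311 and 22 for transcripts with coding-sequence density above the median, and 333 and 3 for well-covered transcripts. Without the trend 77 were lower. On counts, edgeR gave 601 and 5, edgeR with coding-sequence offsets 605 and 4, and DESeq2 322 and 0 (696 and 28 unadjusted). Leaving out a library leaves limma 1 residual degree of freedom and assumes that the lone sample varies like the other group, so these counts of 0 say nothing about stability.

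The count model's 601 higher calls ranged from 429 to 654 without 1 library; of the 601, between 424 (without sup-tRNA replicate 1) and 549 (without control replicate 1) were called again. Its 5 lower calls became 255 with readthrough columns scaled on their own totals and 0 with DESeq2, and ranged from 1 without sup-tRNA replicate 2 to 29 without control replicate 2. For coding sequences, the 208 higher calls ranged from 88 to 188 and the 152 lower calls from 68 to 158 without 1 library, with both lowest values without control replicate 1; DESeq2 gave 88 lower. The 19.2% of well-covered transcripts that more than doubled became 25.2% among transcripts with at least 100 readthrough reads, a filter that favours risen transcripts because it counts sup-tRNA reads, and ranged from 18.0% to 23.6% without 1 library.

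Samples of different groups share only a replicate number. Deviations of same-numbered libraries from their group means correlated at -0.04 for RRTS and 0.39 for coding-sequence counts, over 2 pairs. With the replicate number as a block, limma called 0 higher and 0 lower (825 and 154 unadjusted), the count model 683 higher and 10 lower, and the coding-sequence test 1007 higher and 978 lower. Depth limits the detection of falls: in simulated data the count model found 52% of 4-fold rises and 19.6% of 4-fold falls among 7030 transcripts.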

Other observations

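All tests in this part were chosen after the result was seen, except the count of sample splits, the comparison within the densest transcripts and the comparison with within-group differences of coding-sequence counts.

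The first pattern is that a subset of transcripts rose far more in readthrough than the rest. A factor shared by all transcripts of a library, such as depth, would move log2 values alike, but the distance from the median to the 90th percentile of the log2 change was 2.25 times the larger within-group distance. Background reads added evenly after all stop codons would raise transcripts of like control RRTS and coding density alike. The same ratio had a median of 2.21 over 14 such classes set on control replicate 1 and 2.25 over 13 set on control replicate 2. Over these 27 classes it ran from 1.00 to 3.45 and was under 2 in 10 of them, 7 below an RRTS of 0.05 and 3 at 0.2 to 0.5. Background therefore stays open, whether even or different between transcripts. Low readthrough in control replicate 2 stays open by 1 test. Against control replicate 1 alone 18.0% more than doubled, compared with 7.74% between the sup-tRNA libraries and 13.1% between the control libraries. A test added because that one decided nothing found 512 of the 601 count-model calls again without control replicate 2. The remaining libraries had helped to pick the 601, so finding most of them again was likely and does not settle the question. Rises of more than 4-fold against control replicate 1 alone were seen in 10.1% (sup-tRNA replicate 1) and 9.30% (replicate 2) of well-covered transcripts. Within groups 1.95% and 3.08% differed as much. No reads of control replicate 2 entered these rises, which argues against that library as the source of rises beyond 4-fold. For smaller rises the question stays open. A suppressor tRNA that acts on some transcripts is a candidate explanation, since transcripts that doubled in the first pair of libraries doubled in the second pair 3.28 times as often as all well-covered transcripts (74.9% against 22.9%, and 9.94% of those that had not doubled in the first), which any cause shared by both sup-tRNA libraries may also give. Only 1 of the 3 splits of the 4 libraries into pairs, the real one, gave as many count-model calls (606, against 0 at most for the others), too few splits for a share under 0.05; stop codon identity was not analysed here.

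The second pattern is that coding-sequence footprints were slightly lower on transcripts whose readthrough more than doubled. The coding-sequence count is the denominator of RRTS, so noise in it could produce this. With the rise taken from 1 pair of libraries and the coding-sequence change from the other pair, the differences were -0.048 and -0.052 (log2). Crossing the pairs argues against noise of single libraries only. A coding-sequence fall shared by both pairs raises RRTS in both by itself, so the denominator stays open as an explanation. The difference between groups was 3.43 times the larger within-group difference, which was -0.016 between the sup-tRNA libraries. That within-group value lay 3.28 standard errors below 0 by its own error over transcripts, so errors over transcripts understate the spread between libraries. As a hypothesis, readthrough may lower the footprint density or mRNA level of the affected transcripts; mRNA levels were not analysed here, and a sequence feature shared by these transcripts stays open.

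The third pattern is that well-covered transcripts with long readthrough regions more than doubled less often, from 22.5% for the shortest regions (9 to 48 nt) to 14.6% for the longest (201 to 942 nt). Halving was also more frequent in short regions, at 5.94% against 1.28%, and the net share was 1.24 times as high for the shortest as for the longest, which leaves noise from few reads open as an explanation. Within the 553 transcripts of densest coding-sequence footprints the net share in shorter regions was 0.652 times that in longer ones, but over 5 classes of coding density, from sparse to dense, this ratio was 1.10, 1.21, 0.730, 1.60 and 0.652. The share more than doubled also did not follow density in 1 direction (13.4%, 19.2%, 23.0%, 23.5% and 17.2%), so a part of coverage in the trend stays open. No biological explanation was tested for this pattern.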
